A study of Gallus gallus with 10 samples.

How the data were processed

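RNA was measured by sequencing in intestinal crypts, the pits between villi where stem cells and secretory cells sit, isolated from the duodenum of brown Hy-Line laying hens at peak egg production. Crypts were released with EDTA, a chelator that loosens the epithelium, RNA was taken with TRIzol and RNeasy, and libraries were made with a TruSeq kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, HISAT2 and featureCounts 1.5.0-p3. The genome build and annotation are not given in the sources used here.

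The authors deposited 1 table of FPKM values (fragments scaled to the length of the feature and to a library total) for 19561 features in 10 libraries. Of these features, 17108 have Ensembl chicken gene identifiers and 2453 have numbered identifiers of the authors' own. The table pairs no identifier with a gene symbol. The reference gene table used here (assembly bGalGal1.mat.broiler.GRCg7b, 25635 genes) holds 0 Ensembl identifiers, so 0 identifiers matched. The 31 gene lists planned, with stem cell, Paneth cell and other cell type markers, and a planned panel of single marker genes were therefore not tested, and no list gave a result. Features are named by identifier, at most 2 in each direction per comparison. The rule for naming takes those with the highest and lowest log2 fold change among features that passed the threshold and whose groups did not overlap.

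The labels place 3 libraries under the basal diet (control), 2 under L. sa. + L. ag., 2 under L. sa. + L. av. and 2 under L. ag. + L. av., with the abbreviations as the labels give them. The remaining library is L. ag. + L. av. by its title and L. sa. + L. av. by its description. It entered no group of its own pair and counted only as pair-fed. The labels do not say that each library came from a separate hen, so p-values measure the spread between these libraries, which may be partly technical.

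Low FPKM values were whole multiples of a step specific to each feature, which gave the feature's length, its whole reads and the library total used in the division. Lengths were recovered for 17374 of the 17375 features above 0, and 100.0% of their values above 0 lay within 0.02 reads of a whole number. In simulated data with the same number of libraries, 99.13% of 12089 features with FPKM of at least 1 in at least 2 libraries received the true length, against 74.76% of all 17058 simulated features. Recovered reads per library were 15.3 M to 23.7 M. The totals used in the division were 0.572 to 1.28 times the recovered reads of the library. The median ratio of each library to the geometric mean over libraries was 0.966 to 1.03. The way the authors set these totals is not given in the sources used here.

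Values were tested as deposited, on the log2(FPKM + 1) scale, with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend). A fold change on that scale understates the change of low features. Features with FPKM of at least 1 in at least 2 libraries were tested, 12040 in all. A feature was called at a 2-sided Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons of single diets came from 1 fit with all groups, in which the library of unclear pair had its own coefficient. The comparison of any pair with control was a fit of 7 and 3 libraries. Counts of reads were not the deposited unit, so no count model gave a main result.

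The fits were tested on simulated FPKM for the 12040 features, with 50 features changed at each fold size. For L. sa. + L. ag. against control, 0% of features changed 2-fold, 28% of those changed 4-fold, 82% of those changed 8-fold and 98% of those changed 16-fold were called, with 0.076% of unchanged features. For any pair against control these shares were 12%, 86%, 100% and 98%, with 0.101% of unchanged features. Changed features had a mean FPKM of at least 5. Noise was drawn independently for each feature and library, with no shift shared by the features of a library. The shares hold for such noise and may not carry over to the real libraries.

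The lists, the rule for naming, the test of each comparison, the count over other splits and the following alternatives were fixed before the data were examined. They were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, a robust prior (statmod 1.5.0), library weights, a fit of only the compared groups, a replicate block, a minimum log2 fold change of 1, leaving out each library, and other placements of the library of unclear pair. Division by all recovered reads, limma's voom weights and 2 ways of thinning reads were added after seeing the data. Reads were thinned to an equal total behind the FPKM, which leaves recovered reads unequal, and to equal recovered reads. Classes of abundance and length and the tests of explanations were also added after seeing the data. For the other splits, called features were counted for 100 of the 120 splits of the 10 libraries into 3 and 7. For fold changes that share the control libraries, 100 simulations of unchanged groups against shared controls gave a value for comparison. Their noise too was drawn independently for each feature and library. They give the value without any effect only where no shift is shared by the features of a library.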

Results

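Gene expression was measured in duodenal crypts of laying hens fed a basal diet or the same diet with a pair of lactobacilli for 30 days. The series asks how Lactobacillus regulates gene expression in these crypts, and its title names Lactobacillus salivarius, Lactobacillus agilis, Paneth cells and intestinal stem cells. There were 3 control libraries, 2 for each of the 3 pairs and 1 whose labels name different pairs. Recovered reads per library ranged from 21.7 M to 23.7 M in the 3 control libraries and from 15.3 M to 17.6 M in the 7 pair-fed libraries. Mean depth was 22.4 ± 1.13 M reads (SD, n = 3) under the control diet and 16.5 ± 1.00 M reads (SD, n = 7) with a pair, and the 2 ranges did not overlap (2-sided exact permutation p = 0.0167, the smallest that 120 splits allow for these sizes). Depth and diet therefore differ together, and the labels name no batch. The files do not pair identifiers with gene symbols, so markers of stem cells, Paneth cells and other cell types were not tested.

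Libraries with a pair lay apart from the controls on the first principal component, which held 49.7% of the variance. Control libraries scored -79.4, -54.4 and -45.0. Replicate 1 of L. sa. + L. ag. and replicate 1 of L. ag. + L. av. scored -17.3 and -18.3, and the other 5 pair-fed libraries scored 22.1 to 68.4. These 2 libraries had the most recovered reads of the pair-fed libraries, 17.64 M and 17.55 M. They also had the fewest features at 0, 4317 and 3865. The library of unclear pair, with 17.33 M reads and 4915 features at 0, scored 36.4. Depth and score may thus go together among the pair-fed libraries too. Across the 12040 features, Pearson correlation between libraries of 1 group ranged from 0.900 to 0.974, with Spearman values of 0.878 to 0.962. Libraries of different pairs correlated at 0.914 to 0.970 (Spearman 0.874 to 0.951), and control with pair-fed libraries at 0.797 to 0.945 (Spearman 0.748 to 0.930). Median Pearson values were 0.932 within groups, 0.944 between different pairs and 0.898 between control and pair-fed libraries. Here the library of unclear pair counts as a pair of its own. Libraries of 1 group were thus no more alike than libraries of different pairs. All these values are across features, which are not independent replicates.

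**Figure D1:**
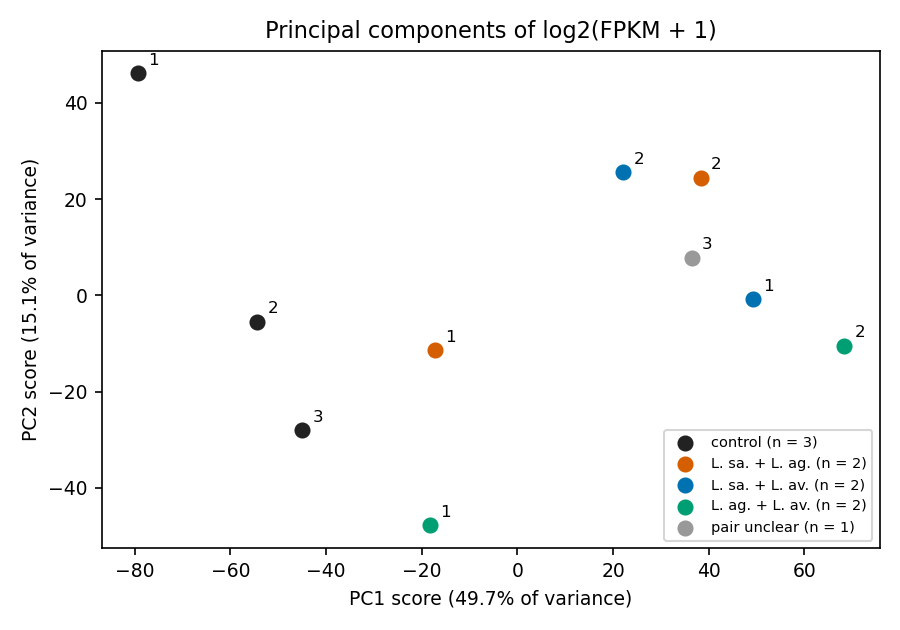
Scores of the 10 libraries on the first 2 principal components of log2(FPKM + 1), with each axis giving its share of the variance and numbers giving the replicate. The 3 control libraries score -79.4 to -45.0 on the first component, below all 7 pair-fed libraries.

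With any pair against control, 2 short features rose from a narrow control range. ENSGALG00000017926, a feature of 329 bp, was at 104 ± 3.92 FPKM in control libraries (SD, n = 3) and at 1868 ± 744 FPKM in pair-fed libraries (SD, n = 7). Its lowest pair-fed value, 1015 FPKM, lay above its highest control value, 108 FPKM. ENSGALG00000025650, of 322 bp, went from 28.2 ± 3.45 (SD, n = 3) to 449 ± 165 FPKM (SD, n = 7), 15.9-fold higher. The log2 fold changes were 4.07 ± 0.34 (SE) and 3.87 ± 0.33 (SE), both with a limma adjusted p of 0.00017.

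Features that fell with any pair included ENSGALG00000009639, of 5746 bp, from 66.5 ± 46.2 FPKM in control (SD, n = 3) to 12.8 ± 7.83 FPKM (SD, n = 7). Its log2 fold change was -2.26 ± 0.55 (SE, limma adjusted p = 0.018). ENSGALG00000015238, of 1767 bp, fell from 65.1 ± 44.6 (SD, n = 3) to 11.5 ± 3.25 FPKM (SD, n = 7), a log2 fold change of -2.25 ± 0.37 (SE, limma adjusted p = 0.015). Both had widely spread control values, 26.0 to 117 FPKM for ENSGALG00000009639, whose highest pair-fed value was 25.1 FPKM. ENSGALG00000009639 did not pass without control replicate 1 (limma adjusted p = 0.087), without control replicate 2 (0.071) or for the mean of the 3 pair groups (0.067), and its adjusted p over all alternatives ranged from 5.9e-06 to 0.087. ENSGALG00000015238 did not pass without control replicate 2 (limma adjusted p = 0.068) or for the mean of the 3 pair groups (0.066), with a range of 2.2e-06 to 0.068.

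In all, limma called 2901 of 12040 features with any pair against control, 1668 higher and 1233 lower, and 1914 of them changed at least 2-fold (1359 higher, 555 lower). The 2 groups did not overlap for 2154 of the called features. Over all tested features the groups did not overlap for 22.1%, where chance gives 1.67%. The count rests on control replicates 1 and 2. It was 125 without control replicate 1, 6 without control replicate 2 and 1936 without control replicate 3, while without the first 2 of these 3650 and 3759 features still had an unadjusted p under 0.05, against 4839 with all libraries. It was 1764 without L. sa. + L. av. replicate 1, 1816 without the library of unclear pair and 8375 with library weights. A contrast of the mean of the 3 pair groups, which leaves out the library of unclear pair, called 10 features. With values divided by all recovered reads, the split turned to 894 higher and 1179 lower, with the median of all features moved to -0.20 from 0.03, and with quantile normalization it was 1310 higher and 1572 lower.

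**Figure D2:**
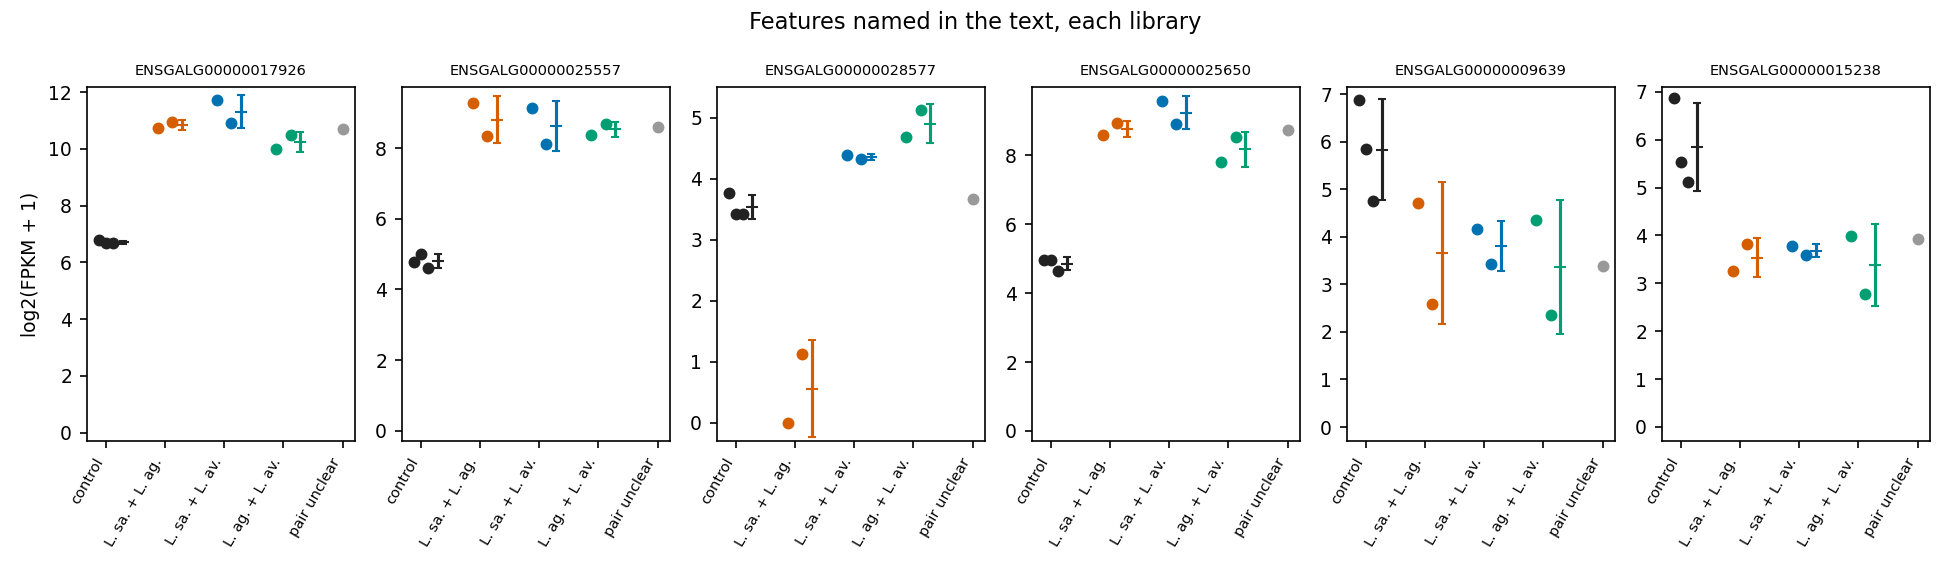
FPKM of the 6 features named in the text in each library, as log2(FPKM + 1) on the vertical axis, with points for libraries and bars for the mean ± SD of these log2 values in groups of at least 2. ENSGALG00000017926 lies between 1015 and 3388 FPKM in the pair-fed libraries and between 101 and 108 FPKM in the controls.

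The change with any pair followed abundance and length. Among 126 features with a mean above 1000 FPKM, the median log2 fold change was 1.31, and 72 were called higher and 0 lower. It was 1.10 between 100 and 1000 FPKM (737 features, 358 higher and 12 lower), 0.50 between 20 and 100 FPKM, -0.02 between 5 and 20 FPKM and -0.14 under 5 FPKM, where 194 were called higher and 646 lower. By length, the median was 0.46 for 1022 features of up to 500 bp and -0.37 for 1875 features above 4000 bp, with 207 higher and 14 lower in the former and 65 higher and 326 lower in the latter. Each of the 7 pair-fed libraries showed a median between 0.13 and 0.72 above the control mean for features of 20 to 100 FPKM, where control libraries lay between -0.02 and 0.03 from the mean of the other controls. These classes use the mean over all 10 libraries, so the change itself helps to set the class. With classes by the control mean, the median under 5 FPKM was 0.01 (418 higher, 398 lower), between 5 and 20 FPKM -0.08, between 20 and 100 FPKM 0.21, between 100 and 1000 FPKM 0.65 and above 1000 FPKM 0.75 (62 features, 19 higher and 1 lower). Features with a control mean above 100 FPKM had a median of 1.31 up to 500 bp (68 features), where those under 20 FPKM had 0.40. The medians were 1.10 and 0.39 between 500 and 1000 bp and 0.35 and 0.15 between 1000 and 2000 bp. They lay closer in longer features, at -0.10 (93 features) and -0.18 between 2000 and 4000 bp and at -0.39 (22 features) and -0.36 above 4000 bp. The scaling moved the medians too. Above 1000 FPKM the median was 0.99 after division by all reads and 0.23 with quantile normalization, which gives every library the same distribution of values. Up to 500 bp it was 0.34 and 0.41, and above 4000 bp it was -0.60 and -0.33. Of the features with the authors' own identifiers, 319 of 1769 were called higher and 34 lower, and of those with Ensembl identifiers 1349 of 10271 were higher and 1199 lower.

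**Figure D3:**
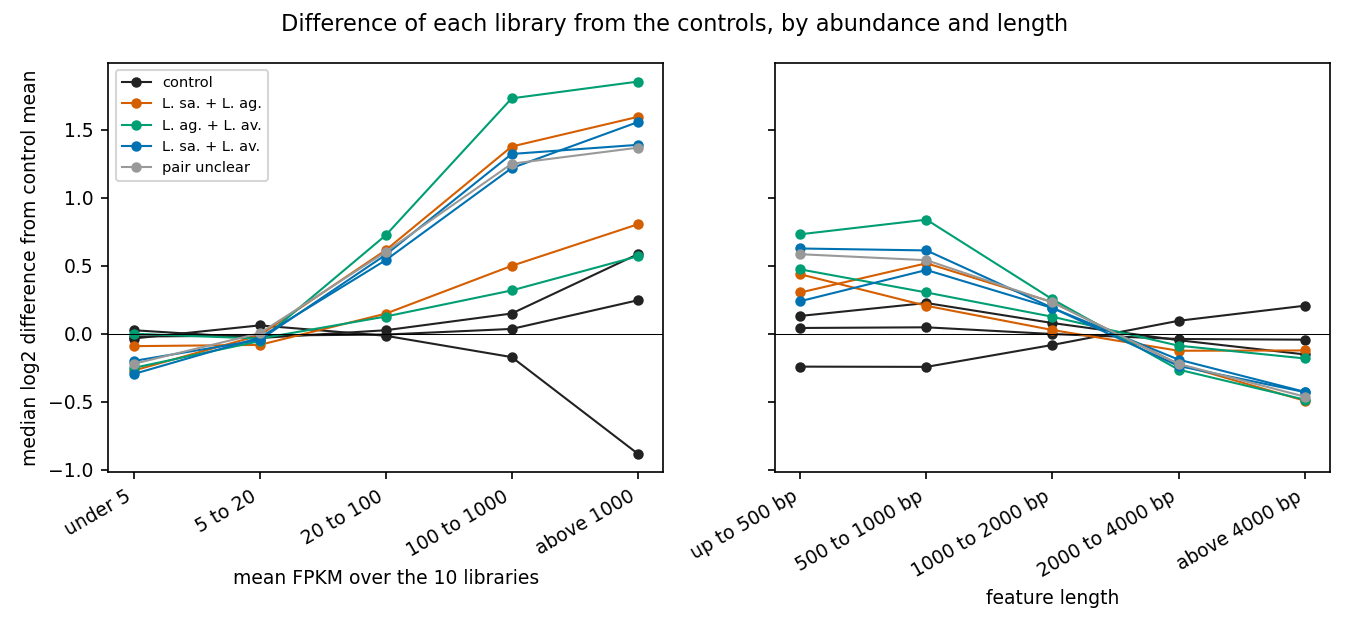
Median log2 difference of each library from the control mean, with features grouped by mean FPKM (left) and by length in bp (right), 1 line per library. Control libraries are compared with the mean of the other controls. For features above 1000 FPKM the pair-fed libraries lie at 0.57 to 1.85 and the controls at -0.88 to 0.58, and above 4000 bp the pair-fed libraries lie at -0.49 to -0.12 and the controls at -0.15 to 0.20, so the groups overlap in both classes.

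With L. sa. + L. ag. against control, ENSGALG00000017926 rose to 1839 ± 219 FPKM (SD, n = 2) from 104 ± 3.92 (SD, n = 3), a log2 fold change of 4.13 ± 0.48 (SE). ENSGALG00000025557, of 287 bp, rose to 472 ± 211 FPKM (SD, n = 2) from 27.0 ± 3.77 (SD, n = 3), 4.01 ± 0.47 (SE) on the log2 scale, both with a limma adjusted p of 0.025. ENSGALG00000028577, of 460 bp, fell from 10.7 ± 1.62 FPKM (SD, n = 3) to 0 and 1.18 FPKM in the 2 libraries, which rest on 0 and 8 reads. Its log2 fold change was -2.97 ± 0.38 (SE, limma adjusted p = 0.036), and it was 19.5 ± 0.69 FPKM (SD, n = 2) with L. sa. + L. av. In all, 5 features were higher and 1 lower, and 1862 had an unadjusted p under 0.05. The size of a fold change against values near 0 depends on the pseudocount. ENSGALG00000028577 was not called with a pseudocount of 0.1 (limma adjusted p = 0.17) or with limma's voom weights (adjusted p = 0.28). The count was 1 without control replicate 3, a lower feature, and none of the calls above was kept. It was 0 without control replicate 1 or 2 and 0 in a fit of only these groups. Without either L. sa. + L. ag. library, none of the calls above was kept.

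With L. sa. + L. av. against control, ENSGALG00000017926 rose to 2647 ± 1049 FPKM (SD, n = 2), a log2 fold change of 4.60 ± 0.48 (SE). ENSGALG00000025650 rose to 623 ± 202 FPKM (SD, n = 2) from 28.2 ± 3.45 (SD, n = 3), 4.38 ± 0.43 (SE) on the log2 scale, both with a limma adjusted p of 0.017. The comparison called 8 features higher and 0 lower, with 3202 at an unadjusted p under 0.05. The count was 4818 with library weights, 879 with the library of unclear pair placed in this group, 1730 in a fit of only these groups, and 0 without control replicate 1, control replicate 2 or L. sa. + L. av. replicate 1. Without L. sa. + L. av. replicate 2, which left 1 library of this pair, none of the calls above was kept.

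With L. ag. + L. av. against control, limma called 0 features, with 2727 at an unadjusted p under 0.05 and 4 called with voom weights. ENSGALG00000017926 was at 1230 ± 304 FPKM (SD, n = 2), 11.8 times the control mean, with a log2 fold change of 3.53 ± 0.48 (SE, limma adjusted p = 0.086). ENSGALG00000025650 had a log2 fold change of 3.32 ± 0.43 (SE, limma adjusted p = 0.076). Both features were chosen after their values were seen. Without L. ag. + L. av. replicate 1, 1303 features were called, and without replicate 2, 18 were.

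Between pairs, ENSGALG00000028577 alone passed. It was lower with L. sa. + L. ag., at 0 and 1.18 FPKM, than with L. ag. + L. av., at 29.3 ± 6.64 FPKM (SD, n = 2), with a log2 difference of -4.34 ± 0.42 (SE, limma adjusted p = 0.017). Against L. sa. + L. av. its log2 difference was -3.79 ± 0.42 (SE, limma adjusted p = 0.057). The call was lost with a pseudocount of 0.1, with voom weights, in a fit of only these groups, and without L. sa. + L. ag. replicate 1 or L. ag. + L. av. replicate 1, with limma adjusted p over all alternatives from 0.0058 to 0.589. Without L. ag. + L. av. replicate 2, 8 features were called. Limma called 0 features for L. sa. + L. ag. against L. sa. + L. av. and 0 for L. sa. + L. av. against L. ag. + L. av., with 196 and 352 at an unadjusted p under 0.05, 1.63% and 2.92% of those tested, and 0 by voom weights in both. The first count was 1 without L. sa. + L. av. replicate 2, and the second was 10 without L. ag. + L. av. replicate 2.

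Log2 fold changes against control had the same sign for 83.9%, 81.9% and 83.4% of features in the 3 combinations of pairs, where simulated unchanged groups gave 63.1%. Across 12040 features, log2 fold changes of L. sa. + L. ag. and L. sa. + L. av. correlated at 0.857, of L. sa. + L. ag. and L. ag. + L. av. at 0.800, and of L. sa. + L. av. and L. ag. + L. av. at 0.817. Unchanged groups simulated against shared controls gave 0.400. The covariances were 0.578, 0.515 and 0.636, where the simulation gave 0.090, so they exceeded it by 0.488, 0.425 and 0.546. L. sa. + L. ag. and L. sa. + L. av. had 4 features called higher in both, where independent lists would share 0.0033, a value that leaves out the shared controls. The 3 control libraries could not be split into parts of at least 2, so part of the excess may come from the shared controls. The simulated noise had no shift shared by the features of a library. Such a shift in the controls could raise all these values without any effect of diet. The excess is therefore not read as an effect shared by the pairs.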

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

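The bound for the test of other splits was set after the count was seen. The tests of feature length and of a control library under a pair label were chosen after their pattern was seen, as were division by all reads and both ways of thinning. Among 13 measures compared over the 7 pair-fed libraries, 1 had a library far from the rest, and chance gives about 1 in 20. That measure was FPKM and not its log2. The chance rate is for libraries of 1 kind, where these come from different pairs.

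ENSGALG00000017926 was at 3388 FPKM in L. sa. + L. av. replicate 1, where the next highest pair-fed library had 1994 FPKM. ENSGALG00000028577 differed between L. sa. + L. ag. and L. ag. + L. av. by a log2 difference of -4.34 in the direct test, at 0 and 1.18 FPKM in the former.

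Of 100 splits of the 10 libraries into 3 and 7, 1 gave as many called features, the real one with 2901, and the highest of the others gave 187. That other split put L. ag. + L. av. replicate 1 with control replicates 2 and 3. A count as large as 2901 is thus unlikely from a random grouping of these libraries, and 1 of 100 is the smallest share possible here. The splits test the count and not single features, and the labels do not say that each library is a separate hen. The count was 125 without control replicate 1, 6 without control replicate 2 and 1936 without control replicate 3. With libraries thinned to equal recovered reads, 96.0% of the called features were called again in the same direction (median of 5 draws). With an equal total behind the FPKM, 91.4% were. Most calls thus did not need the extra reads of the controls. Thinning takes reads from all features in proportion, so it cannot test a technical difference that goes with depth. The authors' scaling as the whole cause is argued against by division by all reads, where 68.4% were called again. That share pools the directions. Division by all reads called 894 higher and 1179 lower, against 1668 and 1233 as deposited, so it holds less for higher calls. What stays open is a technical difference that goes with depth, the diet itself and cells of other types in the crypt preparations. The last could not be tested without gene names. Any batch that the control libraries share stays open too, since the labels give none.

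For the rise of abundant features with any pair, the first tests used the class above 1000 FPKM by the mean over all 10 libraries. With 1 control left out, its lowest median log2 fold change was 1.04, without control replicate 1. After division by all reads its median was 0.99. Within that class, these values argue against a single control library and against the authors' totals as the whole cause. That cut favours features high in pair-fed libraries, and neither test was run with classes by the control mean. Thinning (1.31, and 1.31 with equal recovered reads) decides nothing, since it takes reads from all features in proportion. Features of that class rest on a median of at least 12974 reads in each library. Quantile normalization (0.23) decides nothing either, since it gives every library the same distribution. Depth and a technical difference in the shape of the distribution therefore stay open. Classing features by the control mean lowered the median above 1000 FPKM to 0.75 (bootstrap 95% interval 0.24 to 1.03, 62 features), which leaves open how much of the rise comes from the classing. The bootstrap resampled features and not libraries, so its intervals leave out the spread between libraries. Within length classes, features with a control mean above 100 FPKM lay above those under 20 FPKM by 0.43 over all lengths (bootstrap 95% interval 0.32 to 0.54). The difference was 0.52 up to 2000 bp (0.39 to 0.64) and 0.057 above 2000 bp (-0.13 to 0.43). By class it was 0.91 up to 500 bp, 0.71 between 500 and 1000 bp and 0.19 between 1000 and 2000 bp. The log2(FPKM + 1) scale understates the change of low features, which adds to such a difference where features rise. Length as the whole cause is therefore left open at all lengths. RNA quality, library preparation and the diet stay open as untested. With classes by the mean of all libraries, features above 100 FPKM had a median of 0.65 above 2000 bp (bootstrap 95% interval 0.42 to 0.84, 130 features) and 1.23 in the 733 shorter ones.

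L. ag. + L. av. replicate 1 lay near the controls, correlating at 0.945 with control replicate 3 and at 0.913 with its own replicate. The gap was 0.0309 with equal recovered reads and 0.0301 with an equal total behind the FPKM, so it did not rest on unequal read numbers. Thinning takes reads from all features in proportion, so a technical difference that goes with depth stays open. Over the 1000 features with the smallest p without this library, it lay at 0.381 of the way from the control mean to the mean of the other pair-fed libraries. Control replicate 3 lay at 0.377 when left out in the same way, and the other controls at 0.0446 and 0.0927. The library lay outside the control range for 3 features named from other pairs, with ENSGALG00000017926 at 1015 FPKM against 101 to 108, ENSGALG00000025557 at 331 against 23.4 to 30.9 and ENSGALG00000025650 at 226 against 24.3 to 30.3. These features were chosen for standing apart from the same controls, in fits that include this library, so their position is not independent of the choice. Over 20 features chosen for L. sa. + L. ag. and L. sa. + L. av. with this library and 1 control held out, it lay at 0.604, 0.735 and 0.660. The held-out controls lay at 0.0986, 0.0616 and 0.0268, which goes against a control library under a pair label. The median difference was 0.639 with control replicate 2 (bootstrap 95% interval over features 0.503 to 0.723) and 0.498 with control replicate 3 (0.196 to 0.728). With control replicate 1 it was smallest, at 0.380 (-0.0743 to 0.709). A control library under a pair label therefore cannot be told apart from a weak response by these tests.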

How the results depend on the processing

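Division by all reads, voom weights and both ways of thinning were chosen after the data were seen. Where a group was left with 1 library, that library was assumed to vary like the other groups. The alternatives for gene lists were not run, since 0 identifiers matched a symbol. The cause of these changes was not tested.

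Against control, L. sa. + L. ag. (6 called) fell to 0 in a fit of only the compared groups and to 0 with the replicate block, and ranged from 0 to 1 without single libraries. L. sa. + L. av. (8 called) gave 4 without the filter, 4818 with library weights, 1730 in a fit of only the compared groups, 1 with the replicate block, 879 with the unclear library in this group, 19 after division by all reads, and 0 to 8 without single libraries. L. ag. + L. av. (0 called) gave 5 and 3 with the unclear library as L. ag. + L. av. and as L. sa. + L. av., 4 after division by all reads, 4 with voom weights, and 0 to 1303 without single libraries.

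Between pairs, L. sa. + L. ag. against L. sa. + L. av. (0 called) gave 4 without the filter, 1 with a mean FPKM of at least 5, with library weights, with the unclear library as L. sa. + L. av. and after division by all reads, and 0 to 1 without single libraries. L. sa. + L. ag. against L. ag. + L. av. (1 called) gave 0 with a pseudocount of 0.1, in a fit of only the compared groups and with voom weights, 4 without the filter, 2 after division by all reads, and 0 to 8 without single libraries. L. sa. + L. av. against L. ag. + L. av. (0 called) gave 1 with a pseudocount of 0.1, 1 with the replicate block, and 0 to 10 without single libraries.

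For any pair against control (2901 called), library weights gave 8375, a minimum log2 fold change of 1 gave 1914, leaving out the unclear library gave 1816, the mean of the 3 pair groups gave 10, and single libraries left out gave 6 (control replicate 2) to 3915 (L. sa. + L. ag. replicate 1). It was 125 without control replicate 1 and 1764 without L. sa. + L. av. replicate 1. The other 17 alternatives stayed within 1.5 times, with 2786 for reads thinned to an equal total behind the FPKM and 2841 for equal recovered reads. ENSGALG00000017926 and ENSGALG00000025650 passed under all 24 alternatives of this comparison, with log2 fold changes of 3.17 to 4.27 and 3.34 to 4.02 and adjusted p up to 0.0038. For L. sa. + L. ag. against control, ENSGALG00000017926, ENSGALG00000025557 and ENSGALG00000028577 passed in 9, 8 and 7 of 17 alternatives, the last resting on 0 and 8 reads. No named feature changed direction. Correlations of log2 fold changes between pairs ranged from 0.773 to 0.880, with the ends from leaving out 1 control, where simulated unchanged groups gave 0.50 with 2 controls and 0.40 with 3.

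Libraries with the same number did not deviate together, with 3 of 9 distinct correlations above 0.1 and 4 below -0.1, so the numbers were not taken as pairing. With the replicate block the count for any pair was 2997. The 1 feature called with the block for L. sa. + L. av. against control was none of the 8 called in the main fit. ENSGALG00000028577 did not pass for L. sa. + L. ag. against L. ag. + L. av. with the block (limma adjusted p = 0.076, and 0.0058 to 0.589 over all alternatives), and the 1 feature called there was another. The correlation of same-number deviations in these 2 groups was 0.443.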

Other observations

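The library whose labels name different pairs was close to several pair-fed libraries. Its Pearson correlation across features was 0.923 and 0.970 with the L. sa. + L. ag. libraries, 0.970 and 0.961 with the L. sa. + L. av. libraries, 0.927 and 0.963 with the L. ag. + L. av. libraries and 0.853 to 0.912 with the controls. These values do not place it in either pair. ENSGALG00000028577 was at 11.8 FPKM in it, where control libraries had 9.73 to 12.5 FPKM, L. sa. + L. av. libraries 19.0 and 19.9 FPKM and L. ag. + L. av. libraries 24.6 and 34.0 FPKM.

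The 10 most abundant features held different shares of the summed FPKM of each library. The share was 27.3%, 39.3% and 63.0% in the control libraries and 20.6% to 46.2% in the pair-fed libraries (2-sided exact permutation p = 0.25, n = 3 and 7).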
